A study of Caenorhabditis elegans with 2 samples.

How the data were processed

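Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole late embryos of a transgenic Caenorhabditis elegans line that carries MEC-3 fused at its C terminus to GFP and FLAG. Per the labels, chromatin was sheared by sonication, precipitated with an antibody against GFP, and taken from hermaphrodite animals 4 h after synchronization by egg bleaching. The series holds 1 group of 2 samples, which the labels number as biological replicates 1 and 2. No untreated or control sample was used here. The deposited file list names a control file among the inputs of the peak calls, and that file was not used here.

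The data are region lists that the authors deposited, not reads. Per the deposited file list, a candidate list was made for each replicate from its own alignment, another from the alignments of both replicates together, and a final list from these 3 by the irreproducible discovery rate (IDR), a method that ranks regions by how well replicates agree. Per the labels, the lists are given on the genome builds ce11 and ce10. The aligner, the peak caller, the IDR threshold, the read filters and the number of reads are not given in the sources used here, so the depth of each replicate is unknown. Each region has a position, a summit, a signal value and a q-value. The signal value of a region is the authors' own, as deposited, and its scale is not given in the sources used here, so it was used only to describe, rank or filter regions within a list. The second value is the −log10 of a q-value, also as the authors deposited it, and it was only summarised. The p-value column held no values.

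The lists on ce11 were used for every result, and those on ce10 only as an alternative, with no coordinates carried from one build to the other. Genes came from Ensembl release 115 on WBcel235, the assembly that ce11 names, and sequence from the RefSeq copy of that assembly. The ends of the candidate regions lay within the chromosome lengths of that sequence on all 6 chromosomes. Coordinates are 1-based. Only the 19973 protein-coding genes of the 6 nuclear chromosomes entered the gene tests.

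A region counted as lying in a promoter when its summit fell between 1000 bp upstream and 500 bp downstream of the annotated 5′ end of a transcript of a protein-coding gene, and that gene was called bound when the region was a final peak. A region counted as near a small RNA gene when its summit lay within 500 bp of a tRNA, snRNA, snoRNA or rRNA gene. Final peaks were compared with the 27321 pooled candidate regions that overlap no final peak by 2-sided Fisher's exact tests, with the conditional odds ratio and its exact 95% interval. Shares carry exact Clopper-Pearson 95% intervals. These tests treat regions and genes as independent, although neighbouring regions overlap and 1 peak can lie in the windows of 2 divergent genes, so their p-values can be too small. They describe these lists and not a spread between animals.

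For the replicates, the 457 regions of highest signal in each list were compared, with 1 bp of overlap counting as shared, against 100000 random draws of as many replicate 2 regions in a one-sided permutation test. Each replicate 1 region was matched to the replicate 2 region with the nearest summit within 100 bp for the correlation of signals. The correlation is across regions, which are not independent replicates, and its 95% interval comes from 1000 bootstrap draws of regions.

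Before the data were examined, 16 gene lists, 10 sequence motifs, the windows, the alternatives and the rule for named genes were fixed. The lists are touch receptor neuron, PVD and FLP neuron, neuronal and patterning homeobox, pan-neuronal, ciliated neuron, body wall muscle, hypodermis, intestine, pharynx, cytosolic ribosomal protein, proteasome, translation factor, histone, heat shock protein, collagen and nuclear hormone receptor genes. One symbol of the intestine list, opt-2, matched no gene. The background for lists and for gene classes was the 8225 genes with a pooled candidate region in their window. A gene class is the set of genes that share the letters before the hyphen, and 81 classes had at least 10 genes in the background. Named genes are 12 genes of the touch receptor and PVD neurons, whether bound or not, the gene with the nearest 5′ end for each of the 20 final peaks of highest signal, up to 4 bound members of each list, and up to 3 bound members of each class past the threshold. A gene or region named outside that rule was chosen after its values were seen, which is said where it appears. Motifs were searched within 100 bp of the summit on both strands against up to 10 candidate regions per peak matched on GC content in 5% bins, and all 6-mers were searched in the same way. Benjamini-Hochberg adjustment was made over chromosomes, lists, classes, motifs and 6-mers separately, with a threshold of 0.05 on the adjusted p. A 40 kb window centred on mec-3 was compared with all 40 kb windows of the genome.

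Several steps were added after the data were seen: the split by exon, intron and intergenic place, the kinds of small RNA gene, the union of the neuron lists, the copy number of the summit sequence, the GC-matched small RNA test, the same tests for tRNA and snoRNA genes apart, the comparison with ribosomal protein genes and the search for repeated sequences. A summit window of 100 bp to either side was called multi-copy when at least 50% of its 24-mers occur more than once in the genome, and single-copy when under 10% do. Alternatives covered the peak threshold, each replicate alone, the promoter window, the background, the gene assignment, the distance to small RNA genes, the motif window, the overlap rule, the number of regions, the matching distance and the genome build.

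The tests were checked on simulated peak sets with known answers. Among 100 random sets of 457 candidate regions, the small RNA test fell under 0.05 in 2 and the promoter test in 6, and any of the 16 lists passed in 4 and any of the 81 classes in 3. With 6 genes of the body wall muscle list bound, that list passed in 100 of 100 sets. With AATGCAT written into 10% of the peaks, that motif passed in 20 of 20 sets. Smaller planted effects and shorter lists were not simulated, so the power to find those is unknown. With the ranks of replicate 2 shuffled, the test of shared regions fell under 0.05 in 2 of 20 runs. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.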

Results

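MEC-3 is a LIM homeodomain transcription factor that specifies the touch receptor neurons of Caenorhabditis elegans and acts with the POU factor UNC-86. Its binding was mapped by ChIP-seq of a GFP fusion in whole late embryos, in 2 biological replicates and with no control sample used here. The replicate 1 list held 30000 candidate regions with a median signal of 16.9 and a highest signal of 278, and the replicate 2 list 22464 with a median of 18.6 and a highest of 438. The list called on both replicates together held 27953 regions, and the final list after the irreproducible discovery rate step 457 peaks on ce11, with signals from 77.4 to 722 and a median of 91.1. The number of reads is unknown, and signal values are comparable only within a list. With 1 group, the comparisons are between the replicates, between the final peaks and the remaining candidate regions, and between gene groups.

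The 3 strongest regions were the same in both replicates, and the weakest final peaks were mostly high in 1 replicate. The 3 regions of highest signal were ranked 1, 2 and 3 in each replicate. They lie upstream of K12H4.5, of M01F1.9 and of eel-1, which encodes a HECT-type ubiquitin ligase. Of the 457 top regions of replicate 1, 184 (40.3%, exact 95% interval 35.7 to 44.9) overlapped a top region of replicate 2. Random draws gave a mean of 11.5 and at most 28 (one-sided permutation p = 1e-05, the smallest the draws can give). The share was 64% among the top 25 regions, 46% among the top 100 and 37.4% among the top 1000. Over 7010 regions with matched summits, Spearman's rho between the signals was 0.371 (95% interval 0.348 to 0.393) and Pearson's r of the log2 signals 0.49. At the 483 matched regions that overlap a final peak these were 0.349 and 0.55. Another 22990 replicate 1 regions had no replicate 2 summit within 100 bp. The lists reach down to −log10 q-values of 0.0276 in replicate 1 and 0.0177 in replicate 2, so they include very weak regions. Replicate 1 had 30000 regions on both builds, and whether its list was cut at that number is not given. Unmatched regions therefore cannot be read as sites where binding failed to repeat.

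**Figure D1:**
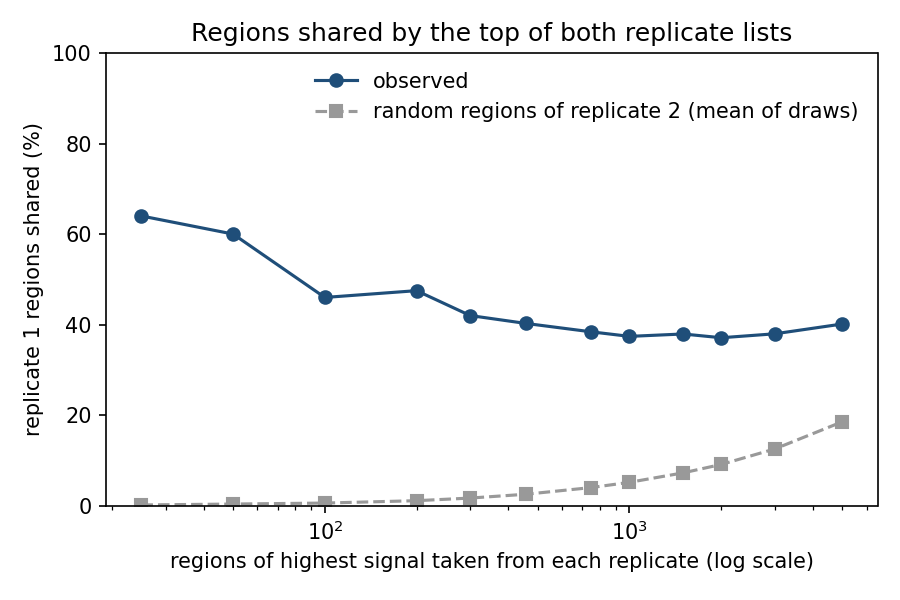
Share of the top regions of replicate 1 that overlap a top region of replicate 2 (vertical axis, %) against the number of regions taken from each list (horizontal axis, log scale). Circles are the observed shares, which fall from 64% at 25 regions to 40.3% at 457, and squares are the mean of random draws, 2.53% at 457.

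The final peaks were the regions of highest signal in the pooled list, with none skipped: 457 pooled regions reached the lowest final signal, and 457 final peaks were found unchanged in that list. All 457 overlapped a candidate region of replicate 1 and of replicate 2. The final list was made from these lists too, so that overlap is largely built in. Of the 457 final peaks, 185 (40.5%) overlapped the top 457 of both replicates, 92 that of replicate 1 alone, 142 that of replicate 2 alone and 38 neither. When the final peaks were ranked by pooled signal, 105 of the 115 strongest (91.3%) overlapped both tops, against 3 of the 114 weakest (2.63%). Pooled signal contains both replicates, so this order is partly built in.

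**Figure D2:**
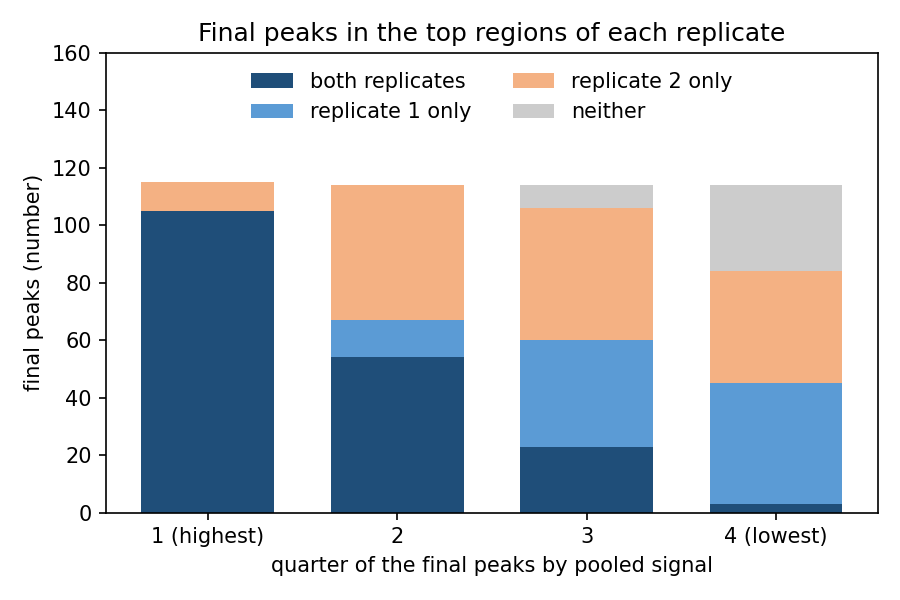
Number of final peaks (vertical axis) in 4 groups of pooled signal, from the strongest on the left to the weakest on the right, by whether they overlap the top 457 regions of both replicates, of 1 replicate or of neither. The number in both tops falls from 105 to 54, 23 and 3.

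The peak of highest signal, 722, covered III:8043788-8044134 on ce11 and lay outside protein-coding genes, 522 bp upstream of K12H4.5. It was 1.5 times the second, at III:3499906-3500207, in an intron of M01F1.8 and 989 bp upstream of M01F1.9. The third, IV:3050484-3050927, lay 602 bp upstream of eel-1, and 86.5% of the 24-mers in its summit window occur elsewhere in the genome. The fourth, V:12303498-12303736, lay on the snoRNA gene C51F7.4 within an intron of frm-7, with F55C5.17 as the nearest protein-coding 5′ end. Peaks of signal 258 and 247 lay upstream of vps-51, which encodes a subunit of a vesicle tethering complex, and of chaf-2, a chromatin assembly factor subunit. The peak of rank 8 (signal 251) lay on the snoRNA gene ZK994.7 in an intron of pxn-1, a peroxidasin gene, and that of rank 12 (signal 223) was 614 bp upstream of sre-23, a chemoreceptor gene, and 55 bp from the snoRNA gene ZK265.10. Upstream of rps-24, which encodes a small-subunit ribosomal protein, there were 2 peaks (signals 204 and 191), and 1 lay upstream of tasp-1 (203). The peaks nearest nas-30, an astacin metalloprotease gene (signal 286), and T28H10.2 (signal 275) were 4965 and 2824 bp from those 5′ ends, with 65.2% and 75.8% multi-copy 24-mers. The other genes nearest a top peak were K10D2.5, Y41D4A.4, Y92H12BR.2, T13C5.6, W03C9.5, Y62F5A.12 and F56G4.6, with signals from 244 down to 182. Of these 20 peaks, 20 overlapped the top regions of both replicates, 16 lay in a promoter window, 3 near a small RNA gene and 5 on multi-copy sequence.

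Final peaks lay in promoter windows of protein-coding genes more often than the other candidate regions, and in coding sequence less often. Of 457 final peaks, 251 (54.9%, exact 95% interval 50.2 to 59.6) had their summit in a promoter window, against 9542 of 27321 other candidates (34.9%). The odds ratio was 2.27 (1.88 to 2.75; Fisher's exact p = 7.13e-18). Of the 251 summits, 213 lay upstream of the closest 5′ end, these at a median of -222 bp, and 77 lay in windows of genes on both strands. Coding sequence held 17.9% of final summits and 34.5% of the others (odds ratio 0.415, adjusted exact p = 1.94e-14), and sequence outside protein-coding genes 52.3% and 31.0% (odds ratio 2.45, adjusted exact p = 3.02e-20). Untranslated exons held 2.41% and 4.57% (adjusted exact p = 0.0309). The share in introns, 27.4% and 29.95%, did not pass the test (adjusted exact p = 0.236). Within 2000 bp of a protein-coding 5′ end lay 353 final peaks. No chromosome passed the test of its share of final peaks: 0 of 6 passed after adjustment and 0 at an unadjusted Fisher's exact p under 0.05. The lowest p was that of chromosome III, with 18.8% against 16.4% (odds ratio 1.18, 0.924 to 1.51; adjusted exact p = 0.597).

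Genes of small structural RNAs stood out among the final peaks. Of 457 final peaks, 77 (16.9%, 13.5 to 20.6) lay within 500 bp of a tRNA, snRNA, snoRNA or rRNA gene, against 535 of 27321 other candidates (1.96%). The share of peaks near tRNA genes, which supply the adaptors of translation, was 9.19% against 1.18% (42 peaks), and that near snoRNA genes, whose products guide modification of ribosomal RNA, 7.0% against 0.630% (32 peaks). snRNA genes, which encode splicing RNAs, lay near 3 peaks, rRNA genes near 0 and microRNA genes, counted apart, near 4. The odds ratio over all 4 kinds was 10.1 (7.72 to 13.2; Fisher's exact p = 6.26e-45). It was 8.46 (5.89 to 11.9) for tRNA and 11.9 (7.78 to 17.7) for snoRNA genes, with adjusted exact p of 1.90e-22 and 1.25e-21. Single-copy windows hold 2 of the 42 tRNA peaks and all 32 snoRNA peaks. Among them the odds ratio was 1.13 (0.135 to 4.20, Fisher's exact p = 0.699) for tRNA and 15.5 (10.1 to 23.2) for snoRNA genes. The tRNA share did not pass there, but that test cannot decide, since the single-copy limit leaves out 40 of the 42 tRNA peaks. Those 40 lay in windows between the single-copy and multi-copy limits, where the tRNA odds ratio was 14.35 (8.79 to 23.5). The snRNA (adjusted exact p = 0.0665), rRNA (1) and microRNA (0.167) shares did not pass.

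Most small RNA genes had no final peak. A final peak lay near 48 of 612 annotated tRNA genes (7.84%) and near 34 of 346 snoRNA genes (9.83%), while 370 and 184 had a candidate region. The summit was inside the gene in 24 of the 42 peaks near tRNA genes and in 6 of the 32 near snoRNA genes, where the median distance was 35 bp. Of the 115 final peaks of highest signal, 28 (24.3%, 16.8 to 33.2) were near a small RNA gene, and of the 114 weakest, 10 (8.77%, 4.29 to 15.5). Over 4 groups of falling signal the peaks near snoRNA genes numbered 19, 7, 4 and 2, and those near tRNA genes 8, 11, 15 and 8. Among tRNA genes with a sequence of their own, 7 of 143 (4.90%) had a final peak, and among those that share their sequence with another, 41 of 469 (8.74%), a difference that did not pass Fisher's exact test (p = 0.157).

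**Figure D3:**
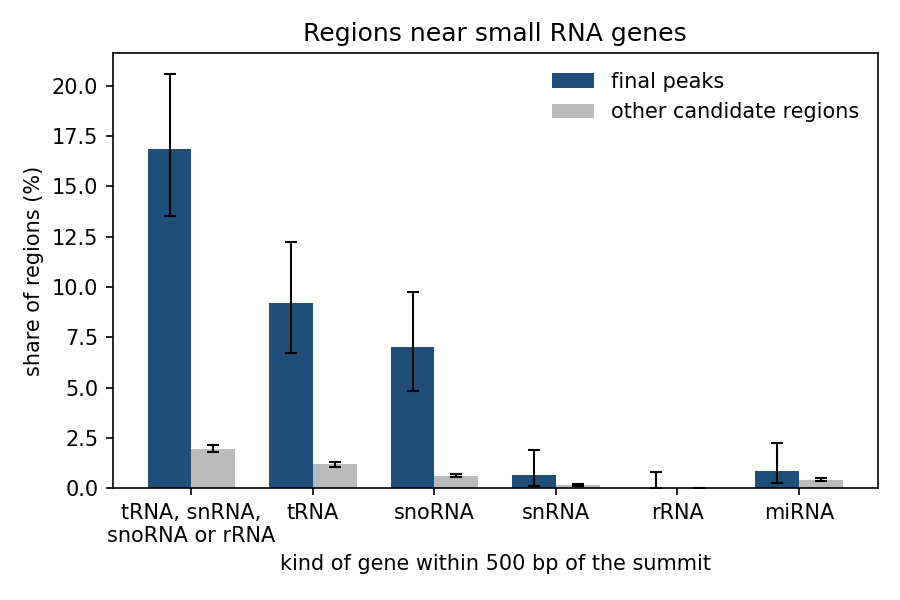
Share of final peaks (dark bars) and of other candidate regions (grey bars) with a summit within 500 bp of each kind of gene (horizontal axis), in percent (vertical axis), with exact 95% intervals. Final peaks lie near tRNA genes in 9.19% and near snoRNA genes in 7.0%, against 1.18% and 0.630%.

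None of the 12 touch receptor and PVD neuron genes followed here had a final peak. mec-3 itself (IV:10458816-10461867), mec-4 and mec-10, which encode subunits of the touch-sensing channel, mec-12, an alpha-tubulin gene, and hpo-30, a claudin-like gene of PVD, had no pooled candidate region in their promoter windows. The pooled candidate nearest to the mec-3 5′ end was 14442 bp away, and the nearest final peak 42198 bp away. The list of replicate 2 alone had a candidate summit at IV:10459690, inside the mec-3 gene but outside its promoter window. For mec-10, mec-4, mec-12 and hpo-30 the nearest candidates were closer, at 1183, 1455, 1531 and 1693 bp, outside the windows. The nearest final peak was 6739 bp from hpo-30, and 36080 bp or more from mec-4, mec-10 and mec-12. Whether the control came from the same transgenic strain is unknown, and this bears on which regions are called at mec-3. The others had candidate regions below the lowest final signal of 77.4, in a list that includes background. unc-86 had signal 61.6 at III:8216204-8216647 (rank 1226), mec-2, a stomatin-like gene, 58.1 (rank 1571), and ptl-1, a tau-like gene, 57.5 (rank 1645). mec-18 had signal 43, acp-2 33.3, mec-17, which encodes a tubulin acetyltransferase, 25.2, and mec-7, a beta-tubulin gene, 24.4 (rank 22560). In the single replicates the unc-86 region ranked 872 and 3269.

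The neuron lists held no bound gene among the final peaks, at sizes where a count of 0 was not unusual. Of all 8225 genes with a candidate region, 331 (4.02%) had a final peak in the window. In the touch receptor neuron list 0 of 11 were bound, where 0.443 would be bound at that share (odds ratio 0, upper bound 9.53; exact p = 1). The PVD and FLP neuron list had 0 of 8, the neuronal and patterning homeobox list 0 of 20, the pan-neuronal list 0 of 17 and the ciliated neuron list 0 of 10. With the top regions of replicate 2 alone, 1 of 17 pan-neuronal and 1 of 11 ciliated neuron genes were bound, and with the window from 2000 bp upstream 1 of 19 ciliated neuron genes. Together, in a union formed after the data were seen, 0 of the 64 genes of these 5 lists were bound against 2.58 at the overall share (odds ratio 0, upper bound 1.41; Fisher's exact p = 0.186). The lists do not cover all neuronal genes, so this does not show that none had a final peak. Outside them, ser-1 (signal 80.6) and cpx-1 (78.4), chosen after their values were seen, had one. Over the 11 touch receptor neuron genes, the median signal of the highest candidate region was 42.7, against 32.5 over all 8225 genes, at the 96.4th percentile of 10000 random lists of 11.

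Bound genes were found in 5 of the 16 lists. The translation factor list had 4 of 24: eif-3.B (signal 125), eif-3.E (105) and eif-3.I (94.6), which encode subunits of initiation factor eIF3, and eif-4A3 (86.3), a helicase of the exon junction complex. The collagen list, of cuticle components, had 4 of 62: col-71 (signal 127), col-85 (111), col-171 (87.9) and col-37 (85.0). The cytosolic ribosomal protein list had 3 of 65: rps-24 (signal 204), rpl-43 (116) and rps-26 (90.6). The summit at col-85 lay inside a tRNA gene, and that at rps-26 lay 115 bp from a snoRNA gene. Both peaks are also among the 77 near small RNA genes, so they are not separate observations. The heat shock protein list had 2 of 11, the chaperone genes hsp-90 (123) and hsp-1 (80.3), and the body wall muscle list 1 of 23, the paramyosin gene unc-15 (80.4). The hypodermis (0 of 17), intestine (0 of 16), pharynx (0 of 13), proteasome (0 of 23) and histone (0 of 20) lists had none, nor did the nuclear hormone receptor list (0 of 94, 3.78 at the overall share).

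No list passed after adjustment over the 16 lists (0 of 16 by Fisher's exact test), and 2 had an unadjusted p under 0.05. These were the translation factor list (odds ratio 4.81, 1.19 to 14.5; exact p = 0.0145, adjusted 0.231) and the nuclear hormone receptor list (odds ratio 0, upper bound 0.949; exact p = 0.0337, adjusted 0.269). Neither stayed under 0.05 with the top regions of replicate 1 alone (2 of 24, odds ratio 2.81, exact p = 0.174, and 1 of 100, odds ratio 0.308, exact p = 0.379). There the collagen (6 of 62, odds ratio 3.35, exact p = 0.0129, adjusted 0.207) and body wall muscle (3 of 22, odds ratio 4.9, exact p = 0.0305, adjusted 0.244) lists fell under it, from 0.316 and 0.612. With replicate 2 alone the heat shock protein list did (3 of 11, odds ratio 6.47, exact p = 0.0197, adjusted 0.157). The nuclear hormone receptor list was also above 0.05 in the upper part of the peaks by signal (exact p = 0.179), in the window from 500 bp upstream (0.113) and with the nearest gene only (0.117). With all protein-coding genes as background, 4 of 33 translation factor genes were bound and the list passed (exact test, adjusted p = 0.0332, the range over its alternatives being 0.0332 to 0.926). Of 81 gene classes 0 passed after adjustment and 4 had an unadjusted exact p under 0.05: eif (4 of 18), dnj (3 of 18), nhr (0 of 94) and tag (4 of 31). The class nhr repeats the nuclear hormone receptor list, and the bound eif genes are those of the translation factor list, so neither is a separate observation. Of the bound tag genes, tag-266 and tag-267 share 1 peak. With the top regions of replicate 2 alone, the class tag, a placeholder name for genes of mixed function, passed with 7 of 27 (exact test, adjusted p = 0.0313, the range over its alternatives being 0.0313 to 1).

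**Figure D4:**
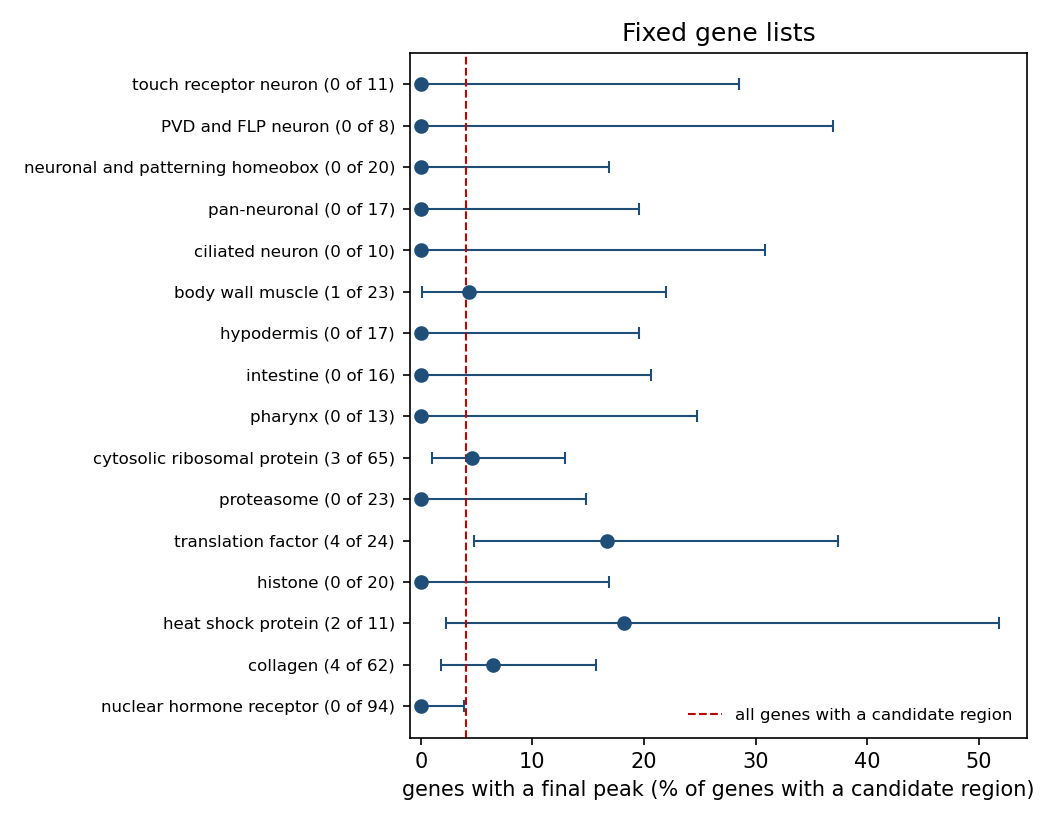
Share of genes with a final peak in their promoter window (horizontal axis, % of the genes with a candidate region) in each of the 16 lists, with exact 95% intervals and the counts beside each name. The dashed line is the 4.02% of all 8225 genes, and it lies within the interval of every list except the translation factor (16.7%, 4.74 to 37.4) and nuclear hormone receptor (0%, up to 3.85) lists.

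The site type bound by UNC-86 with MEC-3 did not pass the test at the final peaks. AATGCAT occurred within 100 bp of 11 of 457 summits (2.41%) and in 2.30% of 4525 GC-matched candidates, and the homeodomain core TAATTA in 3.72% and 4.00%. The odds ratios were 1.05 (0.504 to 1.97) and 0.927 (0.523 to 1.55), each with an adjusted exact p of 0.900. GAGAGA was more frequent, in 26.5% (22.5 to 30.8) against 17.3% (odds ratio 1.72, 1.37 to 2.16; adjusted exact p = 4.00e-05). The cyclic AMP response element TGACGTCA was absent from the final summits, 0 of 457 against 59 of 4525 (1.30%; odds ratio 0, upper bound 0.633; adjusted exact p = 0.0274). The GAGAGA call ended with the top regions of replicate 1 alone (adjusted exact p = 0.0519) and within 50 bp of the summit (0.349, the range over its alternatives being 3.80e-08 to 0.349), and the TGACGTCA call ended in 6 of 7 alternatives (adjusted exact p from 0.0129 to 0.422 over the 7), with an odds ratio that stayed below 1, from 0 to 0.412. The POU octamer ATGCAAAT (0.656% against 1.28%), CACGTG (6.78% against 5.64%), WGATAA (12.9% against 14.1%), TGASTCA (1.09% against 1.33%), TRTTTAC (3.94% against 3.16%) and GGGCGG (12.9% against 10.2%) did not pass. Within 200 bp TRTTTAC (odds ratio 1.64, adjusted exact p = 0.0128, the range over its alternatives being 0.0128 to 1) and GGGCGG (odds ratio 1.52, adjusted exact p = 0.0053, range 1.86e-05 to 0.717) passed. With no GC matching GGGCGG passed as well (odds ratio 2.03), and WGATAA (odds ratio 0.586, adjusted exact p = 1.99e-04, range 1.99e-04 to 1) and TAATTA (odds ratio 0.582, adjusted exact p = 0.0482, range 0.0482 to 1) were less frequent. The background was matched on GC content and not on place. Final summits lay more often in promoter windows than all other candidates (54.9% against 34.9%) and less often in coding sequence (17.9% against 34.5%). Differences in motifs and 6-mers can reflect this, which was not tested.

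In the unguided search, AAAGGG, CTAGGC and CACGCG led the words that were more frequent at the final summits. Of 2080 6-mers, 259 passed after adjustment by Fisher's exact test, 126 more frequent and 133 less frequent. Overlapping words can share occurrences, so these are not counts of separate signals. AAAGGG occurred in 20.1% of final windows against 8.18% (odds ratio 2.83, adjusted exact p = 1.33e-10), and CTAGGC in 16.2% against 5.97% (odds ratio 3.04, adjusted exact p = 4.69e-10). CACGCG (14.4% against 5.15%), GGCCAC (19.5% against 8.46%) and GGCCTA (15.8% against 6.28%) came next by p. The order changed with the windows used: in the 356 single-copy windows CTAGGC, GGCCTA and GGCCAC ranked 1, 2 and 3 by p, CACGCG 13 and AAAGGG 24, and in the 300 that also lack a sequence within 2 mismatches of either of a pair of repeated 12-mers CTAGGC ranked 1, GGCCTA 7, AAAGGG 8, GGCCAC 9 and CACGCG 16, each past the threshold by Fisher's exact test (odds ratio of AAAGGG 2.19 and 2.47). Final summit windows had a GC content of 48.3% ± 8.26 (SD, 457 windows) and the other candidates 42.4% ± 7.71 (SD, 27321 windows) before matching.

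The region of mec-3, the gene fused to GFP in the transgene, held few candidate regions. In the 40 kb centred on mec-3 the pooled list had 1 region, against a median of 11 per 40 kb window, at the 1.16th percentile of 2503 windows. Replicate 1 had 5 (8.57th percentile) and replicate 2 had 3 (6.95th percentile), and the final list 0, as in the median window. Summed signal gave percentiles of 1.34, 8.01 and 6.05. In the 20 kb window the percentiles of the region counts were 1.71, 4.86 and 19.4. The control of the peak calls was not available here, and without knowing its strain a low count at this locus does not show that binding was low.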

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

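The single-copy and GC-matched alternatives were chosen after seeing the data. Counts of calls come from Fisher's exact tests. No paired analysis was possible because the series has 1 group. The promoter share (41.1 to 65.1%) and the small RNA share (9.83 to 20.5%) stayed past the threshold with an odds ratio above 1 under every alternative run (in single-copy windows 2 peaks were near a tRNA gene and 32 near a snoRNA gene), as did the number of shared top regions (permutation p = 1e-05 throughout), and 0 chromosomes passed throughout. Of 77 alternatives, 49 were labelled as the same. For a tested result this meant the same direction and side of the threshold, whatever its size. The promoter and small RNA shares above are among these, with some values outside the main interval. For the correlation and the mec-3 percentile it meant within the spread, and for a count without a test of its own within 1.5 times. Another 7 reversed the direction of a result that did not pass, 12 moved the result, 8 made it weaker and 1 stronger.

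The number of final peaks is 422 on ce10, in a separately deposited list. It is 229 in the upper part by signal, which holds by construction. Matching summits within 200 bp gave a rho of 0.328, outside the interval of the 100 bp value. The number of gene lists past the threshold rose from 0 to 1 with all protein-coding genes as background, which also counts genes without a candidate region, and with each replicate left out it was 0. The number of gene classes was 1 without replicate 1 and 0 without replicate 2. The number of motifs, 2, became 1 in the upper part of the peaks, 0 to 1 with a replicate left out, 0 within 50 bp, 3 within 200 bp, 5 with no GC matching and 1 in single-copy windows. The percentile of the mec-3 window rose from 1.16 to between 6.95 and 8.57 with a replicate left out. The cause was not tested for these.

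AATGCAT turned from an odds ratio above 1 to one below it in the upper part (2.18% of peaks), without replicate 1 (1.53%, and 2.63% without replicate 2, where it stayed above), within 50 bp (0.219%) and with no GC matching (2.41%). TAATTA turned from below 1 to above it in the upper part (5.68%), without replicate 1 (5.47%, and 1.31% without replicate 2, where it stayed below) and in single-copy windows (4.21%). In that order the odds ratios were 0.89, 0.652, 0.22 and 0.941 for AATGCAT and 1.02, 1.11 and 1.10 for TAATTA, none of these 7 passed, and the cause was not tested. Depth is unknown, so it could not be used to set a limit on weak binding.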

Other observations

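The genes of this paragraph were chosen after their values were seen. Several of the strongest promoter peaks lay between divergent genes. The peak upstream of vps-51 (signal 258) was also 256 bp upstream of lin-35, the retinoblastoma homologue, and that at K10D2.5 (244) was 645 bp upstream of prp-19, a splicing factor gene. A peak of signal 190 lay 806 bp upstream of rab-7, an endosomal GTPase gene, and 900 bp upstream of mex-1, a maternal RNA-binding protein gene. Others lay upstream of fib-1, the fibrillarin gene (163), and of snr-1, a spliceosomal protein gene (167), and a peak of signal 158 was 428 bp upstream of npp-6, a nucleoporin gene, and 253 bp inside spd-5, a centrosome gene. The rab-7 peak was nearer to W03C9.5 (193 bp), and the snr-1 peak was nearer to snx-13 (197 bp against 414 bp). The fib-1 peak was also 176 bp upstream of mut-15. No list of the kinds of gene described here was fixed, and their share was not tested.

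The pooled gap without a candidate summit around mec-3 ran from IV:10446659 to IV:10481851, 35192 bp, against a median gap of 2021 bp, and 59 of 27947 gaps were as long. It was 16669 bp in replicate 1, where 519 of 29994 gaps were as long, and 4555 bp in replicate 2, where 7107 of 22458 were, so the long gap is not seen in replicate 2.

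In the next 3 paragraphs, the single-copy and GC-matched tests and the repeat search were added after the data were seen, and the tests of ribosomal protein genes, of tRNA and snoRNA genes apart, of the number of genes in the touch list and of near copies of the repeats were chosen only after the result was seen. No biological difference between groups was tested, since the design has 1 group.

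The final peaks lay near small RNA genes at an odds ratio of 10.1 (8.98, 6.02 to 13.0, among single-copy windows). The values argue against more explanations for snoRNA than for tRNA genes. For snoRNA genes all 32 peaks had a single-copy window and the odds ratio among such windows was 15.5 (10.1 to 23.2), which argues against multi-copy sequence, whereas for tRNA genes it cannot be told apart: 2 of 42 peaks had a single-copy window (odds ratio 1.13, 0.135 to 4.20), and among windows with 10 to 50% multi-copy 24-mers the odds ratio was 14.3 (8.79 to 23.5), so that leaving out repeated sequence also leaves out most tRNA peaks. Against GC-matched candidates the odds ratio was 9.24 (6.64 to 12.8), 7.79 (5.04 to 11.9) for tRNA and 9.38 (5.58 to 15.7) for snoRNA genes, so GC content is not the whole cause. Within the same 500 bp, ribosomal protein genes had an odds ratio of 1.33 (0.158 to 4.97). Of the 63 near a candidate, 2 had a final peak (3.17%, 0.387 to 11). Both upper bounds lay below the lower bounds of snoRNA genes (odds ratio 11.9, 7.78 to 17.7, and 34 of 184, 18.5%, 13.2 to 24.9). This argues against strong transcription as such for snoRNA genes only if ribosomal protein genes are strongly transcribed in these embryos, which was not measured. The comparison also rests on 2 ribosomal protein peaks, and the one at rps-26 lies 115 bp from a snoRNA gene and counts in both sets. For tRNA genes (48 of 370, 13.0%, 9.72 to 16.8) the intervals of these shares overlap, and strong transcription cannot be told apart. Binding of many factors at these genes, or an antibody signal that does not depend on MEC-3, stays open, since no other factor and no control precipitation was analysed here.

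The touch receptor neuron list had no bound gene. Its size is a candidate explanation, since the chance of 0 bound among 11 genes was 0.636 at the overall share. Binding below the threshold of the final peaks, such as in the few cells of a whole embryo that make these neurons, could also leave the list empty. The median signal of its candidate regions was at the 96.4th percentile of random lists, below the level set in advance for this explanation and above the level set against it, so it cannot be told apart from the list's size with 11 genes.

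Of 78785 12-mers in the final summit windows, ACGAAAAGGGGA was the most frequent (22 final peaks, 36 other candidates), and AGAGGAGTACAC led in the windows without it (21 and 22), with 373 and 150 copies in the genome. Both were picked on these peaks, so their odds ratios (38.3 and 59.7) are not independent evidence. Such repeats may carry the enriched 6-mers, yet in single-copy windows 88.1% of the 126 kept at least the square root of their odds ratio. That test does not decide, since 56 of 356 single-copy final windows (15.7%, against 4.07% of the others) lay within 2 mismatches of either sequence. With those left out as well, 77.8% kept it and 35 of the 126 were still past the threshold and more frequent, in 300 final windows (36 of all 6-mers, and 53 in both directions), which argues against these near copies as the whole cause, while the calls that were lost and more diverged copies stay open. The background was not matched on promoter or coding place, so that difference stays open too.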
